A study of Pimephales promelas with 16 samples.

How the data were processed

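Testes of adult male fathead minnows (Pimephales promelas) were profiled on 16 one-colour arrays, 8 from fish exposed in the water to 17alpha-ethinylestradiol (EE2), a synthetic estrogen, at 25 ng/L for 96 hours and 8 from control fish. Total RNA was extracted with Trizol and labelled with Cy3, per the labels. Each array held the RNA of 1 fish, and the design text calls the 8 samples of a group biological replicates. The fish numbers in the labels were used to name the samples. No number occurred in both groups.

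The deposited scanner files give spot intensities, which the authors extracted with Agilent Feature Extraction 10.7, per the submitters' processing notes; the file headers give version 10.7.1.1. The processed signal is an intensity after background subtraction and detrending, per the file headers, and is not normalized between arrays. The files also give other values per spot, such as marks of 0 or 1 for spots well above background, saturated or of uneven brightness, per the file headers. A table of the authors' processed values holds the same arrays. The values of that deposited table are on a log2 scale: each column correlated at 0.989 to 0.999 with the log2 processed signal of its array, had a median of 7.13 and held 7763 spots at a floor of 3.50. The columns share one distribution, so they had been quantile normalized. The exact steps behind them are not given in the sources used here. The number of columns of other samples was 0.

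The array had 62372 spots, of which 1319 control spots were left out, and 49849 different probes. Of these probes, 41517 had 1 spot, 7973 had 2 and 359 had 10. The log2 of the processed signal was taken and each array's 75th percentile was subtracted, so all levels are log2 values relative to that percentile. Spots marked as outliers were left out and spots of the same probe were averaged. Probes were tested if they were well above background on at least 4 of the 8 arrays of either group, which left 41626. EE2 was compared with control by limma 3.58.1 in R 4.3.3 (lmFit and eBayes, group as the only term), with Benjamini-Hochberg adjustment over all tested probes and a threshold of 0.05. Files were read with the R package data.table, version 1.17.8. Correlations over fish and plots used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.

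The share of the total sum of squares between the groups was tested against all 12870 assignments of the 16 arrays, and the correlation of fold changes between slides against all 70 assignments of the arrays of slide 2. Both were one-sided exact permutation tests. The file headers placed the arrays on 2 slides, each with 4 control and 4 EE2 fish. Slide was therefore tried as a block, and each slide was fitted alone. The other alternatives were normexp background correction with an offset of 50, quantile normalization, centring on the median, the authors' processed values, other filters on dim probes, slide with array row, an intensity trend with robust estimation, array weights, and leaving out each array in turn. The normexp alternative used the median spot signal, since the mean spot signal is not among the columns used here.

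The procedure was tested on simulated data for this comparison over 41626 probes, with 50 probes changed at each fold size. With all arrays, 22% of the changes of 2-fold, 74% of 4-fold, 88% of 8-fold and 96% of 16-fold were recovered, with 9 false calls among 149. The simulated noise was normal and independent between probes. The real arrays were not so, since their first component held 31.3% of variance. The planted changes also eased the adjusted threshold, with 149 calls against 7 in the data. These shares may thus be too favourable for the real arrays. Signal over background was similar between groups: 78.9% ± 3.93 of probes were well above background in control fish and 79.0% ± 6.55 in EE2 fish (SD, n = 8, two-sided exact permutation p = 0.951). The median SD between fish within groups was 0.62 on the log2 scale, over the tested probes with complete values. Between spots of one probe on one array it was 0.11, measured only on the 359 probes with 10 spots. The number of arrays limits the precision.

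The files used here do not pair the probes with genes. The probes carry identifiers of the array's design, and 0 of them occurred in the gene table given for the assembly fPimPro1.hap1.1. The rule fixed beforehand for naming genes, which took genes past the threshold by size of change, and the 21 gene lists fixed beforehand, which covered estrogen response, steroidogenesis, gonad differentiation, germ cells and other cell types, could therefore not be applied. Among the probes past the threshold, the 2 with the largest rise and the 2 with the largest fall are named by identifier. A probe that was well above background on none of the arrays of a group has no measured level there. Its fold is given against a floor. Where some arrays of a group measured a probe, their number is given. For the floor, the higher of the probe's own value and the lowest signal well above background was taken on each control array. The EE2 mean was set against the mean of these. An undetected probe can lie above that lowest signal, so this fold is not a lower bound.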

Results

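The data were 16 arrays of adult fathead minnow testis, 8 from control fish and 8 from fish exposed to EE2 at 25 ng/L for 96 hours. The signal at the 75th percentile of an array averaged 900 ± 250.3 in control fish and 982 ± 138 in EE2 fish (SD, n = 8). The difference between the group means was not beyond that of other assignments of the 16 arrays (two-sided exact permutation p = 0.435). The series title frames the exposure as low in dose and asks about expression networks of gonad differentiation. The comparison made here was EE2 against control for each probe.

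A small set of probes rose steeply in the testis of EE2 fish, and 2 fell. The probe SINGLET_4251 rose 28.1-fold (95% confidence interval 13.5 to 58.4), from -4.36 ± 1.28 in control fish to 0.45 ± 0.83 in EE2 fish (log2 relative to the array's 75th percentile, SD, n = 8). It was well above background on 5 of the 8 control arrays and on all 8 EE2 arrays. UF_Ppr_AF_109055 rose 25.8-fold (13.6 to 48.8), from -4.16 ± 1.05 to 0.53 ± 0.79 (SD, n = 8), and was above background on 7 control arrays. The log2 fold changes were 4.81 (SE 0.50, limma adjusted p = 0.000432) and 4.69 (SE 0.44, limma adjusted p = 0.000187). The lowest EE2 fish lay above the highest control fish for both probes. The sizes depended on the processing: with normexp the log2 fold changes were 3.58 (limma adjusted p = 0.000122) and 3.37 (limma adjusted p = 3.99e-05). The normexp setting also used the median spot signal and added an offset. These choices were not tried apart, so the smaller sizes cannot be put down to any of them.

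The falls were smaller than these 2 rises. UF_Ppr_AF_105540 fell 2.98-fold, from -1.29 ± 0.46 to -2.87 ± 0.18 (SD, n = 8), a log2 fold change of -1.58 (SE 0.20, limma adjusted p = 0.00257). SINGLET_24675 fell 2.89-fold, from -1.29 ± 0.47 to -2.82 ± 0.22 (SD, n = 8), a log2 fold change of -1.53 (SE 0.20, limma adjusted p = 0.00502). All 8 EE2 fish lay below all 8 control fish for both. The files used here do not pair these probes with genes, so the number of transcripts behind them is not known.

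**Figure D1:**
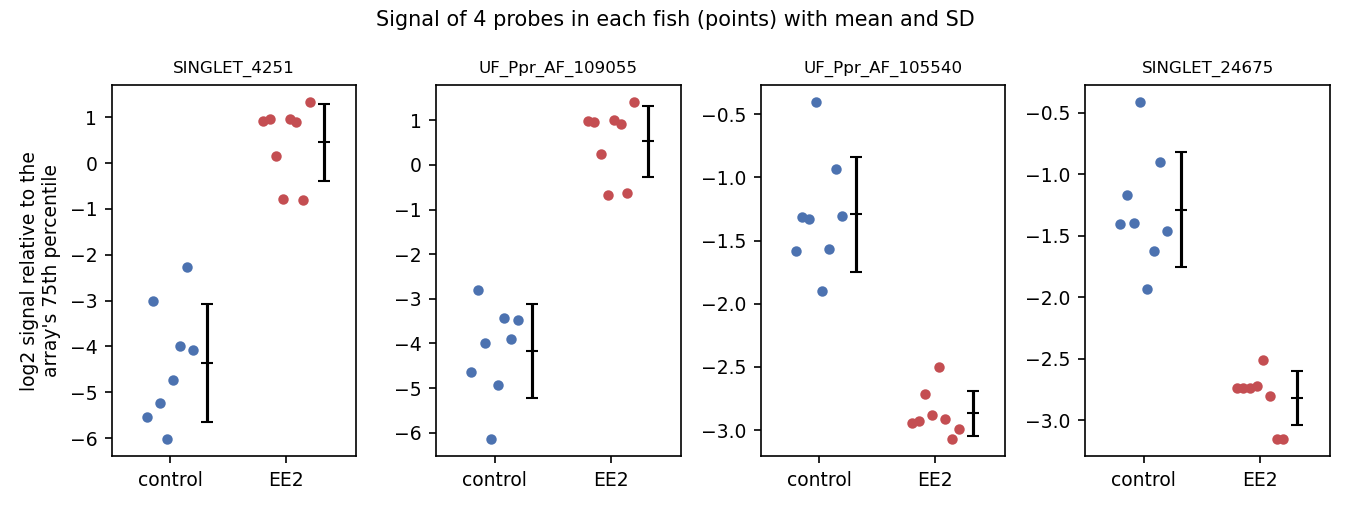
Signal of the 2 probes with the largest rise and the 2 with the largest fall among those past the threshold, in log2 units relative to each array's 75th percentile. Points are single fish, 8 per group, and bars are the mean and SD; the groups do not overlap in any panel.

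Of 41626 probes tested, 7 passed the threshold, 5 higher and 2 lower in EE2 fish. Another probe rose 21.3-fold (9.79 to 46.2), from -2.49 ± 0.74 to 1.92 ± 1.44 (SD, n = 8, limma adjusted p = 0.00203). A further one was not well above background on any control array and was on all 8 EE2 arrays, so its control level was not measured. Its rise was 13.3-fold against the floor on the processed signal, and its fitted change had a limma adjusted p of 0.000432. With normexp its fitted log2 fold change was 1.65 (limma adjusted p = 0.00488), a smaller rise, so 13.3-fold is not a lower bound. The remaining rise was 2.51-fold (limma adjusted p = 0.0474), and this call was lost with slide as a block (limma adjusted p = 0.0558). At an unadjusted limma p under 0.05 there were 3723 probes, where 2081 would be expected by chance, and 43.5% of them were higher in EE2 fish. That split depended on scaling: 56.0% were higher after quantile normalization, 57.8% after centring on the median and 56.1% in the authors' processed values.

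With slide as a block, 6 probes passed. All 7 probes kept their direction on each slide, with rises of 1.06 to 5.26 on slide 1 and 1.59 to 5.10 on slide 2 on the log2 scale. The falls were -1.71 and -1.64 on slide 1 and -1.44 and -1.43 on slide 2. These probes were picked from both slides together, so their shared direction is no independent test of agreement. None of the 7 passed within either slide, each with 4 fish per group, where 1 other probe passed on slide 1 and 3 others on slide 2. The interaction of group and slide was called by limma for 0 probes, with 999 at an unadjusted p under 0.05 against 2081 expected. The array of the control fish numbered 14 stood apart from the others. Without it 37 probes passed, 19 higher and 18 lower, among them all 7 of these probes. The count was 11 without EE2 fish 6 and 11 without EE2 fish 11.

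**Figure D2:**
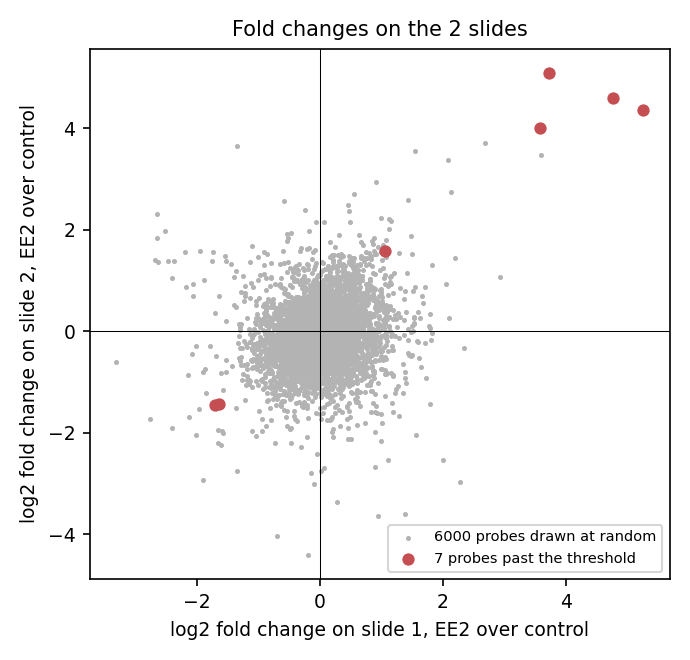
Log2 fold change, EE2 over control, on slide 1 (horizontal) against slide 2 (vertical). Grey points are 6000 probes drawn at random and red points the 7 probes past the threshold, which lie in the same direction on both slides. These 7 were picked from both slides together.

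With all fish, the share of variation between the groups was not beyond that of other groupings of the arrays. The groups held 7.53% of the total sum of squares, against a median of 6.27% over all assignments of the arrays (one-sided exact permutation p = 0.240). Within slides the share was 8.35% (one-sided exact permutation p = 0.197). Without control fish 14 it was 12.1%, against a median of 6.75% (one-sided exact permutation p = 0.0202).

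**Figure D3:**
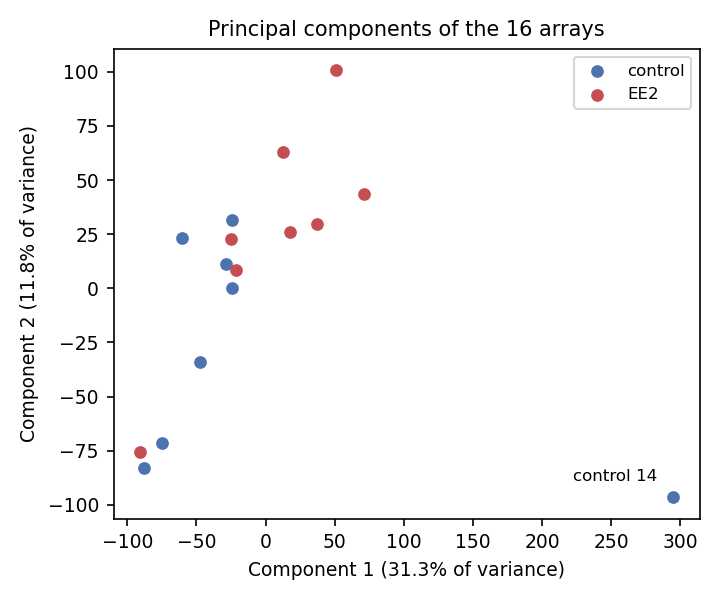
Scores of the 16 arrays on the first component (31.3% of variance, horizontal) and the second (11.8%, vertical), coloured by group. Control fish 14 lies at 294.7 on the first component, and the other arrays lie between -90.7 and 71.5.

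Fold changes on the slides, which share no fish, correlated weakly across probes. Pearson's r was 0.180 (one-sided exact permutation over arrays, p = 0.214), and 58.3% of probes had the same sign on both. Probes are not independent replicates, which is why arrays were permuted. Without control fish 14, r was 0.328 (one-sided exact permutation p = 0.0857).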

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

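The tests of control fish 14 below were all chosen after its values were seen. Among 28 sets of 8 values searched for a single distant fish, 3 had one, where chance gives about 1.40. Control fish 14 had a median correlation of 0.801 with the other arrays, against 0.922 to 0.943 for the other control fish. On the array of control fish 2, the median log2 signal of the ERCC control spots was 3.996, against 2.01 to 2.80 on the other control arrays. The probe with the smallest rise past the threshold had a level of -3.83 in control fish 7, against -3.47 to -3.18 in the other control fish.

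Control fish 14 differed broadly: 4262 probes lay over 4-fold above the mean of the other controls and 5430 over 4-fold below. Noise on the array is argued against by the SD between spots of one probe, 0.118, within 0.0913 to 0.130 on the other arrays. This SD covers only the 359 probes with 10 spots. Its 75th percentile signal was the lowest of the 16 (580.9) and its spike-in signal relative to that percentile the highest (log2 -0.08, the next -0.63), as a low amount of labelled RNA would give, but as the whole cause this is argued against by the brightest probes, where its deviations had an SD of 1.59 against at most 0.56. A label exchanged with an EE2 fish cannot be told apart from the label given by these values. Control fish 14 lay below the lowest EE2 fish at 4 of the 5 probes that rose over 8-fold without it. At all 7 probes past the threshold it lay outside the range of EE2 fish, on the control side. Those 7 also passed without it, but were picked with it counted as a control. Of the 37 probes called without it, 22 (59.5%) were nearer to the EE2 mean. Its r was low with every array, 0.754 to 0.853 with EE2 arrays and 0.755 to 0.804 with control arrays, so r cannot decide this. A far position on an axis that other fish share stays open. Its deviation correlated at 0.51 in size across probes with the first component of the other 15 fish. The same value for each other fish was 0.013 to 0.463. Those components included control fish 14, so the values are not alike and cannot decide this. No biological explanation was tested, since the design names no group that would give one.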

How the results depend on the processing

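Leaving out control fish 14 together with the slide block or quantile normalization was chosen after seeing the data; the other alternatives were fixed before the data were examined. The count of 7 probes became 14 with normexp background, 12 with only probes above background on all 16 arrays, 13 with an intensity trend and robust estimation, 221 with array weights, 1 on slide 1 alone and 3 on slide 2 alone. It was 32 without control fish 14 with slide as a block and 148 without it after quantile normalization. Leaving out 1 fish at a time gave 6 to 37 probes: 37 without control fish 14, and 11 without EE2 fish 6 or EE2 fish 11. The 3723 probes at an unadjusted p became 8986 with array weights, 1858 on slide 2 alone, 7398 and 8205 in the last-named settings without control fish 14, and 2794 to 7659 with 1 fish left out, 7659 without control fish 14. With array weights, control fish 14 had the lowest weight, 0.117, the next being 0.541 for EE2 fish 19. Those 221 calls held 36 of the 37 made without control fish 14. The cause of these changes was not tested. The share of variation between groups, 7.53%, was 7.06% to 12.1% with 1 fish left out and passed the threshold only without control fish 14, at 12.1% and, after quantile normalization, 12.6%. The correlation between slides was 0.077 to 0.328 with 1 fish left out and passed in no setting run. Of the 7 probes, 6 stayed past the threshold with any 1 fish left out, and the weakest lost its call in 13 of 16 such fits. No direction of the 7 reversed. No paired analysis was possible because the groups share no replicate numbers. Gene list tests and means over probes of a gene were not run, since the files used here do not pair probes with genes. Without a filter on dim probes 6 passed. The sizes of the 2 named rises, which start from dim control levels, depended on the setting. With normexp their log2 fold changes were 3.58 and 3.37, against 4.81 and 4.69. The normexp setting changed the background correction and the spot signal used and added an offset, and which of these lowered the sizes was not tested.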

Other observations

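The tests of array scaling, of control fish 14 as a source of the excess, and of the size of the rise were chosen after the results were seen; so were the splits balanced over slides, the splits for groups that do not overlap and those at an unadjusted p without control fish 14. The remaining counts over splits and the detection count were planned before. Among the 8 EE2 fish, 3 of the rising probes, the 2 named ones and the one seen only in EE2 fish, varied together. Since the files used here do not pair probes with genes, probes of 1 transcript cannot be told apart from separate genes in these pairs. Pearson's r was 0.959 to 0.999 and Spearman's rho 0.90 to 0.95 over the 3 pairs, with exact permutation p of 0.000273 to 0.00154 for r and 0.00114 to 0.00456 for rho. Adjusted over the 11 pairs tested, p for r was 0.00300 to 0.00564, and without the 2 farthest fish r was 0.759 to 0.996. In each pair these were the fish farthest from the median of 1 of its probes, so they could differ between pairs. The 2 falling probes had r = 0.79 (exact permutation p = 0.0300, adjusted 0.0825) and rho = 0.76 (exact permutation p = 0.0368), and r = 0.86 without the 2 farthest fish. The probe that rose 21.3-fold gave r of 0.33 to 0.34 with those 3 (exact permutation p of 0.419 to 0.424, adjusted 0.583). Its rho with them was 0.52 to 0.60 (exact permutation p of 0.132 to 0.197). Without the 2 farthest fish, picked on the named probe, r was 0.16 with each of the 2 named probes. With the third it was 0.90, the fish being picked on the probe that rose 21.3-fold. These r rest on different fish, so whether this probe varied with the 3 is not decided. The probe with the smallest rise gave r of 0.12 to 0.16 with those 3 (exact permutation p of 0.692 to 0.761), and r of -0.60 to -0.42 without the 2 farthest fish. With the probe that rose 21.3-fold its r was 0.61 (exact permutation p = 0.106, adjusted 0.233).

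Probes whose groups did not overlap numbered 48, 21 higher and 27 lower, where 0.0155% of probes, or 6.47, would be expected by chance. Over all 6435 splits of the arrays, 91 gave at least the 47 such probes found among those with complete values, with 376 in the highest other (exact permutation p = 0.0141), so such counts vary widely between splits. A switch across the detection limit was rare: 6 probes were well above background on at least 7 EE2 arrays and at most 1 control array, and 3 the reverse. All splits of the arrays gave at least these 9 probes often (exact permutation p = 0.323).

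Splits of the fish into other groups of the same sizes bear on the counts. Of 100 splits of the 16 fish, 3 gave at least 7 probes, the real one included, and the highest other gave 186. That count is many times the real one, and why that split gave it was not tested. Without control fish 14, 3 of 100 gave at least 37 probes and the highest other gave 59. Among 100 splits drawn to keep the balance over slides, the real one alone (1) gave at least 7 probes, with 2 in the highest other, and the real one alone (1) gave at least 37 without control fish 14, with 6 in the highest other. The share as large was under 0.05 in each of these draws, but 100 splits measure such a share only roughly. Among the balanced splits within the first draws, 2 of 43 were as large, with 186 in the highest other. Without control fish 14, 3 of 39 were as large, a share above 0.05, with 59 in the highest other. Chance is therefore not excluded for these counts. At an unadjusted p, 9 of 100 splits gave at least 3723 probes and the highest other gave 7321, and 9 of 100 balanced splits did, with 6540 in the highest other, so chance is not excluded for that excess with all fish. Without control fish 14 the real split alone (1 of 100) gave at least 7659, against 6021 in the highest other and 7034 in the highest other balanced one.

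The excess at an unadjusted p was set against technical sources. It did not come from control fish 14, since 7659 probes passed without it. It did not come from scaling alone, since the lowest count under another scaling or source of values was 3669. The majority of lower probes may come from scaling, because up to 57.8% were higher under another scaling.

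A hypothesis was that EE2 fish with a larger rise of the 3 probes lie further along a main axis of variation. Against the first component of the 15 fish other than control fish 14, r was 0.89 (exact permutation p = 0.00102, adjusted 0.00305), rho 0.90 (exact permutation p = 0.00456), and r 0.82 without the 2 farthest fish; this axis was where the relation was noticed, and it was built in part from the same EE2 fish. On the first component of the 7 other control fish, r was 0.35 (exact permutation p = 0.442, adjusted 0.442), rho 0.14 (exact permutation p = 0.752), and r -0.54 without the 2 farthest fish, so the relation was not seen on an axis free of treated fish. Against the brightness of the array, r was 0.59 (exact permutation p = 0.107, adjusted 0.161), rho 0.29 (exact permutation p = 0.501), and r 0.59 without the 2 farthest fish. In each relation the 2 farthest fish were those farthest from the median of the axis score or of the brightness. These are 3 relations over 8 fish, and neither the axis nor brightness can be decided for this number of fish.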
